A study of Mus musculus with 16 samples.

How the data were processed

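RNA sequencing read counts from 16 libraries of mouse bladder urothelium were analysed, 4 libraries in each of 4 groups. Per the labels, a tamoxifen-inducible Cre recombinase was driven by the Krt5 or the Krt8 promoter, a YFP reporter marked the recombined cells, and YFP-positive cells were sorted from the bladder. The normal groups carried reporter alleles only, and the transformed groups carried floxed Trp53 and Pten. Tamoxifen was given at 100 mg/kg per day for 4 days at 2 months of age. Normal mice were sampled 7 days later and transformed mice 3 months later, at 5 months of age. Each group held 2 libraries from male and 2 from female mice. The replicate numbers follow the order of the samples and pair nothing between groups.

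The deposited tables hold raw read counts per gene, unfiltered and filtered, and the deposited regularized log table holds log2 values. The authors' processing notes name STAR 2.4.2a, Subread, featureCounts and DESeq2 with the builds GRCm38 and mm10. The annotation release and the strand setting are not stated, so reads from antisense or overlapping genes cannot be separated. The labels describe the library kit, the read layout and the amplification in more than 1 way, and these were left unresolved. The authors' filtered table holds 21965 of the 46983 genes, each with a total of at least 5 counts, and its values equal those of the unfiltered table. Of the identifiers, 46488 matched the GENCODE mouse M21 annotation, and the 495 without a match held 0.0188 to 0.0331% of the counts of a library.

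The unfiltered counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14180 genes. Libraries were scaled by TMM factors, and CPM values are counts per M of the scaled library total (M for mega). A quasi-likelihood model with 1 coefficient per group was fitted to all 16 libraries. Its common dispersion was 0.0626, a biological coefficient of variation of 25%. The contrasts of 2 groups, 4 in all, compared transformed against normal cells in each line and KRT5-traced against KRT8-traced cells in each state. A further contrast tested the difference between the responses of the lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes of a contrast were called. Log2 fold changes have their standard errors (SE), and group means of CPM have their standard deviations (SD). A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group. A group with 1 to 3 counts has a ratio of pooled counts with an exact 95% interval, and both cover counting error only.

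Gene lists were fixed before the data were examined, as were the model, the thresholds, the rule for named genes and the alternatives other than those called added. The 24 lists covered luminal and umbrella cells, basal cells, squamous differentiation, p53 targets, cell cycle, sterol and fatty acid synthesis, FOXO-responsive genes, glycolysis and hypoxia, mesenchymal transition, interferon response, inflammatory mediators, xenobiotic and oxidative stress response, immediate early and heat shock genes, ribosomal proteins and mitochondrially encoded genes. Marker lists covered fibroblasts, smooth muscle, endothelium, immune cells, class II antigen presentation, nerve and Schwann cells, red blood cells, prostate and seminal vesicle, and sex labels. Lists with at least 3 tested members, 22 in all, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01. The adjusted p of a list covers the lists of its comparison. Member counts are given over all genes tested and, where that count differs, again adjusted over the list alone.

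Named genes in a comparison were the 7 largest rises and the 7 largest falls among called genes. They needed a mean of at least 10 CPM in the higher group, no overlap between the 4 libraries of each group, and a gene symbol that is not a clone name. Up to 4 members of each list with the smallest adjusted p were added, with Trp53, Pten, Krt5, Krt8, Upk2, Upk3a, Krt20, Krt14 and Trp63. For the difference of responses the 5 largest in each direction were taken. Genes outside this rule appear under other observations and were chosen after their values were seen.

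The pipeline was tested on simulated counts with 50 genes changed at each of several folds. For KRT8-traced cells edgeR recovered 14% of genes changed 1.5-fold, 48% at 2-fold, 86% at 4-fold and 96% at 8-fold, with 7 false calls. For the difference of responses it recovered 6%, 22%, 82% and 88%, with 3 false calls. In the same simulation DESeq2 1.42.0 made 19 false calls and limma-voom made 5. Camera found the changed list and called 0 of the others. Genes were simulated independently of each other, so this could not show false list calls that come from genes that move together. Far fewer genes were changed in it than were called in the data. The cutoff depends on that share, so recovery in the data may differ.

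Alternatives changed 1 choice at a time. They were relative log expression factors, library totals alone, no filter, a filter at 10 CPM, the genes of the authors' filtered table, DESeq2, limma-voom, limma on the authors' log2 values, glmTreat against a fold of 1.5, RNA integrity number (RIN) or sex as a term, each sex alone, only the groups compared, and each library left out in turn. List tests were repeated with an estimated correlation, fry, library totals alone, sex as a term, and without shared genes. Leaving out 3 libraries that stand apart (KRT5 normal replicate 1 and KRT5 transformed replicates 2 and 3) and keeping protein-coding genes only were added later. Figures were drawn with Matplotlib 3.10.9.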

Results

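Gene expression was measured by RNA sequencing in YFP-sorted bladder urothelial cells of outbred mice, in 16 libraries with 4 in each group. The cells had been marked by a Cre recombinase under the promoter of Krt5, a keratin of basal epithelial cells, or of Krt8, a keratin of luminal epithelial cells. They are called KRT5-traced and KRT8-traced. Transformed cells had been targeted for combined loss of p53 (Trp53) and PTEN (Pten), a tumor suppressor that opposes PI3K signaling, and normal cells had not. Total counts ranged from 10747693 to 24296968 per library (10.7 to 24.3 M), with group means of 16.9 ± 3.75 M (SD, n = 4) in normal KRT8-traced, 14.8 ± 4.04 in normal KRT5-traced, 16.3 ± 5.36 in transformed KRT8-traced and 14.8 ± 3.24 in transformed KRT5-traced cells. Normal libraries had 17587 to 18484 genes detected and transformed libraries 19227 to 20498. RIN ranged from 9.3 to 9.7 in KRT8-traced and from 9.6 to 10 in KRT5-traced libraries. Transformed mice were 5 months old and normal mice 2 months old, so the state of the cells cannot be told apart from age, time since tamoxifen or reporter allele. The libraries are treated as separate animals, and the p-values of single genes measure the spread between them. Camera p-values compare the genes of a list with the other genes, and the Fisher and binomial p-values take genes as units. Xist and Y-linked genes matched the sex label of all 16 libraries, and 0 of 10 prostate and seminal vesicle genes passed the count filter. The leading principal component held 41.2% of the variance and the next 21.3%.

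Of the targeted genes, Trp53 was lower in transformed cells of both lines and Pten in those of the KRT5-traced line. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, GRCm38) had 76.0 ± 2.84 CPM (SD, n = 4) in normal KRT8-traced cells and 46.1 ± 8.03 in transformed KRT8-traced cells. In KRT5-traced cells it had 116 ± 31.8 CPM in normal and 20.7 ± 6.04 in transformed cells. The fall was 4 libraries against 4 without overlap in both lines, with a log2 fold change of -0.72 (SE 0.20, adjusted p = 0.0197) in KRT8-traced and -2.50 (SE 0.22, adjusted p = 5.33e-07) in KRT5-traced cells. The falls differed between the lines by -1.78 (SE 0.29, adjusted p = 0.00455). Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160) fell in KRT5-traced cells, from 78.8 ± 7.98 to 42.4 ± 3.79 CPM, with a log2 fold change of -0.89 (SE 0.12, adjusted p = 3.56e-05). In KRT8-traced cells Pten had 56.6 ± 5.66 CPM in normal and 53.1 ± 7.48 in transformed libraries, a log2 fold change of -0.09 (SE 0.12, adjusted p = 0.637), and the difference between the lines was -0.80 (SE 0.17, adjusted p = 0.0192). Counts per gene do not resolve deleted exons. The Trp53 call in KRT8-traced cells ended without KRT8 transformed replicate 1 (log2 fold change -0.61, adjusted p = 0.0599), and its adjusted p ranged from 0.00375 to 0.57 over the alternatives. The difference between the lines was -0.89 in male mice (adjusted p = 0.203) and -2.66 in female mice (adjusted p = 0.000701) for Trp53. For Pten it was not called in either sex alone (adjusted p = 0.179 and 0.201) or against a fold of 1.5 (adjusted p = 0.519).

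**Figure D1:**
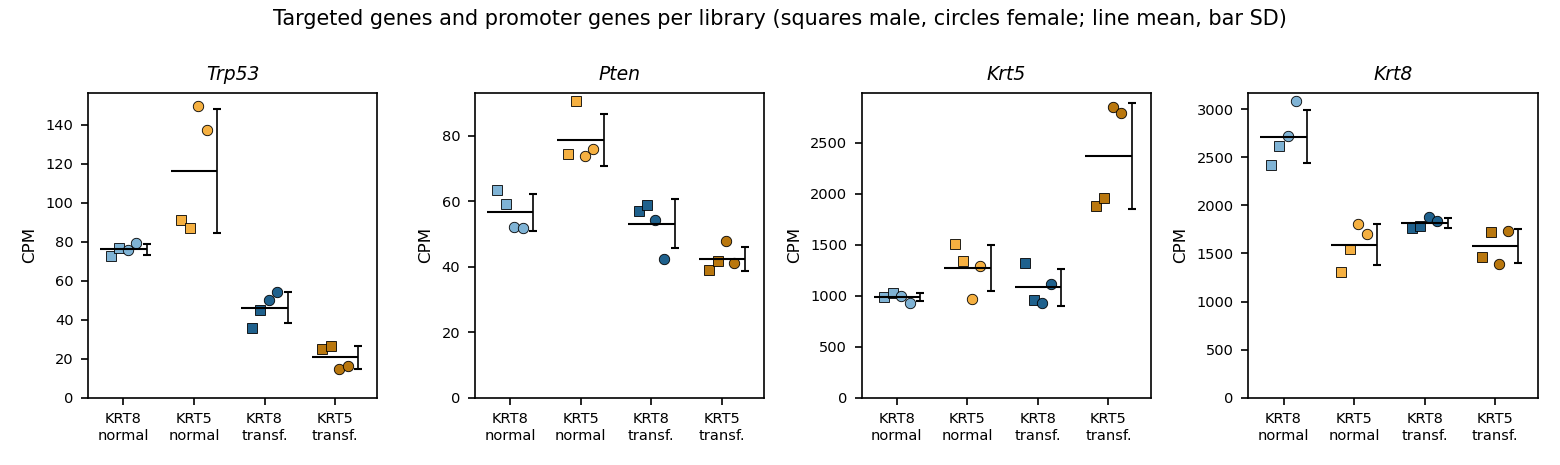
CPM of Trp53, Pten, Krt5 and Krt8 on linear axes from 0, with each library as a square (male) or circle (female), a line at the group mean and a bar for the SD (n = 4). Trp53 lies between 35.5 and 54.1 CPM in transformed KRT8-traced and between 14.9 and 26.6 in transformed KRT5-traced libraries, below all normal libraries.

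Normal KRT5-traced and KRT8-traced cells were compared to ask how cells marked from a basal and a luminal keratin promoter differ 7 days after labelling. KRT5-traced cells had less of the uroplakins that cover the urothelial surface and more of the basal transcription factor Trp63. Upk2 had 810 ± 117 CPM (SD, n = 4) in KRT8-traced and 197 ± 21.6 in KRT5-traced cells, and Upk3a had 5233 ± 1050 and 1214 ± 288. Krt20, a keratin of umbrella cells, had 222 ± 70 CPM in KRT8-traced and 48.4 ± 17.6 in KRT5-traced cells. Trp63 had 335 ± 67.8 and 684 ± 33.7 CPM. The log2 fold changes, KRT5-traced minus KRT8-traced, were -2.04 (SE 0.22, adjusted p = 5.94e-06) for Upk2, -2.11 (SE 0.26, adjusted p = 1.96e-05) for Upk3a, -2.20 (SE 0.27, adjusted p = 2.1e-05) for Krt20 and 1.03 (SE 0.20, adjusted p = 0.000957) for Trp63. Krt8 was lower in KRT5-traced cells (-0.77, SE 0.12, adjusted p = 0.000178), while Krt5 had a log2 fold change of 0.37 (SE 0.17, adjusted p = 0.085) and Krt14 of 2.24 (SE 1.30, adjusted p = 0.182).

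Of the 25 luminal and umbrella cell genes tested in normal cells, 16 were lower and 2 higher in KRT5-traced cells (17 and 3 adjusted over the list alone), among them the surface antigen gene Psca at -3.79 and Grhl3, a transcription factor of umbrella cells, at -1.63. Of 22 basal cell genes, 18 were higher and 1 lower (20 and 1 adjusted over the list alone), among them the laminin receptors Itga3 at 2.53 and Bcam at 1.42 and the hyaluronan receptor Cd44 at 1.33. In camera the adjusted p was 7.22e-06 for the luminal list (adjusted p = 0.0523 with an estimated correlation) and 3.94e-08 for the basal list (adjusted p = 0.301 with an estimated correlation). Inflammatory mediators were higher in normal KRT5-traced cells in 14 of 19 genes and lower in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 5.55e-08; adjusted p = 0.205 with an estimated correlation). They included the adhesion molecule Icam1 at 3.18, the growth factor Csf2 at 3.57 and the NF-kB regulators Tnfaip3 at 2.30 and Nfkbia at 1.51. Glycolysis and hypoxia genes were higher in 11 of 21 and lower in 0 (12 and 0 adjusted over the list alone), with the glucose transporter Slc2a1 at 1.64, hexokinase Hk2 at 2.00 and the angiogenic factor Vegfa at 2.03 (camera adjusted p = 0.000167; adjusted p = 0.578 with an estimated correlation). KRT5 normal replicate 1 stood apart on that list, with a mean log2 CPM of 7.67 against 7.32 to 7.36 in the other KRT5 normal libraries, and 11 were higher without the 3 libraries that stand apart. Cell cycle genes were higher in 15 of 36 and lower in 2, the same counts adjusted over the list alone (camera adjusted p = 0.00658; adjusted p = 0.705 with an estimated correlation). All 8 mitochondrially encoded genes were lower, with mt-Cytb at -0.87 (camera adjusted p = 0.000335; adjusted p = 0.536 with an estimated correlation). Ribosomal protein genes were lower in 8 of 30, and in 0 adjusted over the list alone (camera adjusted p = 0.00202; adjusted p = 0.734 with an estimated correlation).

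Of 27 p53 targets, 10 were higher and 5 lower in normal KRT5-traced cells (11 and 5 adjusted over the list alone), with the death receptor Fas at 3.15 and the cell cycle inhibitor Cdkn1a at 1.16. Of 14 FOXO-responsive genes, 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with the pro-apoptotic gene Bcl2l11 at 1.81. Interferon response genes were lower in 8 of 24 and higher in 1, including Bst2, a restriction factor of enveloped viruses, at -1.62. Of 14 mesenchymal transition genes 6 were higher, with the transcription factor Snai2 at 2.81, while KRT5 normal replicate 1 stood apart in fibroblast genes, with 246 CPM of Col1a1 against 16.3 to 24.4 in the other KRT5 normal libraries. Without the 3 libraries that stand apart, 6 mesenchymal genes were higher and 3 lower. These lists and those not named for this comparison had camera adjusted p from 0.0603 to 0.93. The median and the camera direction differed in sign for the squamous (median 0.38), fibroblast (0.55), sterol (0.03) and immune (below 0) lists. All 4 tested red blood cell genes were lower in KRT5-traced cells, with Hba-a2 at least 68.2-fold lower, although globin genes share reads with near-identical copies (camera adjusted p = 0.00131; adjusted p = 0.301 with an estimated correlation).

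Among the largest rises in normal KRT5-traced cells was Nrcam, a neuronal cell adhesion gene, which had 48.9 ± 16.5 CPM (SD, n = 4). A single count in normal KRT8-traced cells gave it a ratio of 2960 (95% interval 532 to 117000). The Notch ligand Dll1 rose from 9.86 ± 3.41 CPM in KRT8-traced to 232 ± 25.3 in KRT5-traced cells, a log2 fold change of 4.56 (SE 0.34, adjusted p = 3.46e-07). Other rises were in Guca2a (3.86), which encodes guanylin, the aldehyde oxidase Aox3 (3.83) and the sphingomyelin synthase Sgms2 (3.69). Cd200r4 was at least 426-fold higher but had 0.067 CPM in KRT5 normal replicate 3, and it and Hmga1b (5.59) share reads with related copies. The largest falls were in Dmgdh (-4.85, SE 0.38, adjusted p = 6.11e-07), a mitochondrial enzyme of choline breakdown, the amino acid transporter Slc38a1 (-4.42) and the class II antigen presentation gene H2-Eb1 (-4.37). They were followed by the glycosyltransferases Gcnt3 (-4.06) and Fut9 (-4.02), Sprr2g (-3.93) and Shisa9 (-3.89). In total 2654 genes were higher and 2924 lower in KRT5-traced cells, of which 1129 and 1048 differed at least 2-fold. With RIN as a term, which goes with the line of the mice, 642 genes were called.

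**Figure D2:**
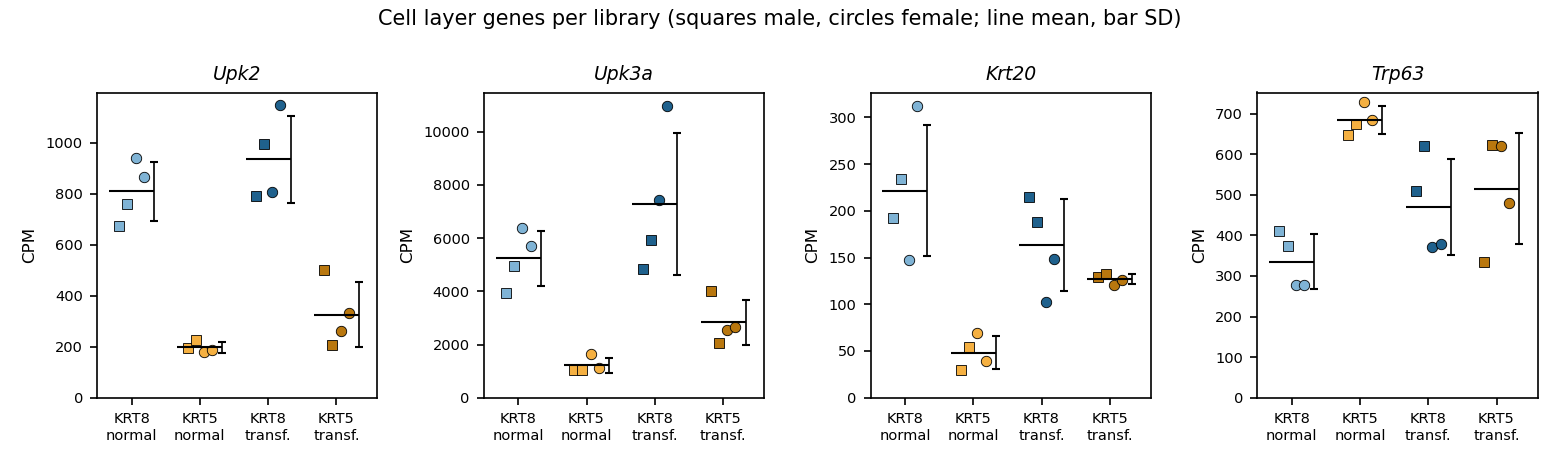
CPM of Upk2, Upk3a, Krt20 and Trp63 on linear axes from 0, with each library as a square (male) or circle (female), a line at the group mean and a bar for the SD (n = 4). Mean Upk2 is 810 CPM in normal and 935 in transformed KRT8-traced libraries, and 197 and 326 in KRT5-traced libraries.

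Transformed KRT5-traced and KRT8-traced cells were compared to ask which of these differences were present 3 months after Trp53 and Pten were targeted. KRT5-traced cells had lower uroplakins, with 326 ± 127 CPM of Upk2 (SD, n = 4) against 935 ± 170 and a log2 fold change of -1.52 (SE 0.22, adjusted p = 0.000493). Krt5 was higher in KRT5-traced cells, at 2369 ± 522 against 1080 ± 184 CPM (1.13, adjusted p = 0.000598). Krt20 had 127 ± 5.31 CPM in KRT5-traced and 163 ± 49.2 in KRT8-traced cells (-0.36, adjusted p = 0.475), and Trp63 had 515 ± 137 and 470 ± 119 (0.13, adjusted p = 0.78). In total 633 genes were higher and 635 lower in transformed KRT5-traced cells. Of these, 411 were also higher and 483 also lower in normal KRT5-traced cells, where independence would give 118 and 131. These comparisons share the dispersions of the same fit, so independence is not a strict reference.

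Luminal and umbrella cell genes were lower in transformed KRT5-traced cells in 10 of 25 and higher in 0 (12 and 0 adjusted over the list alone), including the uroplakins Upk1a at -1.16 and Upk3b at -0.93 and the sorting nexin Snx31 at -1.28. The camera adjusted p was 3.42e-06, and 0.0456 with an estimated correlation. Basal cell genes were higher in 7 of 22 and lower in 0 (11 and 0 adjusted over the list alone), with the basal keratin Krt15 at 1.58 and Bcam at 0.98 (camera adjusted p = 2.21e-09; adjusted p = 0.237 with an estimated correlation). Squamous differentiation genes were higher in 6 of 15 and lower in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00423; adjusted p = 0.424 with an estimated correlation). KRT5 transformed replicate 3 stood apart in these genes, with 209 CPM of the stress keratin Krt6a against 19.8 to 34 in the other libraries of its group and 758 CPM of Krt14. Without the 3 libraries that stand apart, 0 squamous and 0 glycolysis genes, 4 basal genes and 7 luminal genes were called. Glycolysis and hypoxia genes were otherwise higher in 3 of 21 (8 adjusted over the list alone, camera adjusted p = 2.34e-07; adjusted p = 0.424 with an estimated correlation), with Hk1 at 0.70. Xenobiotic and oxidative stress genes were higher in 8 of 19 and lower in 2 (9 and 5 adjusted over the list alone), with the aldehyde dehydrogenases Aldh1a1 at 1.39 and Aldh3a1 at 1.80 and the quinone reductase Nqo1 at 1.36 (camera adjusted p = 0.00303; adjusted p = 0.177 with an estimated correlation). KRT8 transformed replicate 3 stood apart in Cyp1a1 of this list, at 198 CPM against 15.6 to 20.9 in the other libraries of its group.

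Mesenchymal transition genes were higher in transformed KRT5-traced cells in 3 of 14 with Snai2 at 1.92 (camera adjusted p = 0.012) and inflammatory mediators in 3 of 19 (5 adjusted over the list alone) with the cytokine Il1a at 2.56 (0.00845), and mitochondrially encoded genes were lower in 3 of 8 (6 adjusted over the list alone, 0.000766). Each had adjusted p = 0.424 with an estimated correlation. Immediate early and heat shock genes were higher in 2 of 18 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0306; adjusted p = 0.521 with an estimated correlation), and KRT5 transformed replicate 2 stood apart in Hsph1, a heat shock protein gene, at 1330 CPM against 213 to 236. The smooth muscle list had a median of 1.12 and a camera adjusted p of 0.00537 (adjusted p = 0.424 with an estimated correlation), while its 1 called member, Mylk, was lower at -0.67, a call that ended in 6 fits that left out a library (adjusted p up to 0.109). The p53 targets were higher in 5 of 27 and lower in 2, with Gdf15, a stress cytokine gene, at 1.99. The remaining lists of this comparison had camera adjusted p from 0.132 to 0.953, and of these the ribosomal (-0.02) and fibroblast (-0.11) medians lay below 0 with a camera direction above it. Nrcam was again higher in KRT5-traced cells, at 8.81 (SE 0.39, adjusted p = 5.29e-10), followed by Fgfbp1 (5.53), a carrier of fibroblast growth factors, the estrogen receptor gene Esr1 (3.38, SE 0.32, adjusted p = 2.7e-05), Ern2 (3.10), the adenylate kinase Ak1 (3.09), the endothelin Edn2 (2.94) and Krt6a (2.74). The largest falls were in Dmgdh (-3.65), Bhmt2 (-3.56), a methyltransferase that acts on homocysteine, Atp6v0e2 (-3.25), Aldh3b3 (-3.09), Cyp1a1 (-2.69), H2-Eb1 (-2.55) and Fut9 (-2.51). Without KRT8 transformed replicate 3 the Cyp1a1 difference was -0.88 (adjusted p = 0.202). Without KRT5 transformed replicate 3 the Krt6a difference was 1.39 (adjusted p = 0.047), and it was not called without the 3 libraries that stand apart (1.26, adjusted p = 0.135). The Edn2 call also ended in 5 fits that left out a library, at 2.57 to 2.96 with adjusted p up to 0.0763. Without KRT8 transformed replicate 3, 712 genes were called in place of 1268, and with RIN as a term 75.

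Transformed and normal KRT8-traced cells were compared to ask what differed in these cells after Trp53 and Pten were targeted and 3 months had passed, with no fall of Pten seen in this line. Chemokines that attract neutrophils fell, Cxcl2 from 90.2 ± 43 to 0.433 ± 0.286 CPM (SD, n = 4) and Cxcl1 from 145 ± 77.7 to 5.33 ± 2.26. The log2 fold changes were -7.70 for Cxcl2 (SE 0.58, adjusted p = 2.57e-07) and -4.79 for Cxcl1. Trac, a constant gene of the T cell receptor, rose from 0.0937 to 17.2 ± 3.51 CPM (7.61, SE 0.57, adjusted p = 2.57e-07). Uroplakins did not pass the test, with Upk2 at 0.21 (adjusted p = 0.52) and Upk3a at 0.48 (adjusted p = 0.182), while Krt8 fell from 2712 ± 277 to 1815 ± 52.2 CPM (-0.58, adjusted p = 0.00353). Krt14 had a log2 fold change of 3.84 (adjusted p = 0.0492) that rested on KRT8 transformed replicate 1, at 172 CPM: without it the log2 fold change was 1.51 (adjusted p = 0.396), and 9 other fits that left out a library also ended the call. In total 1447 genes were higher and 1550 lower, of which 941 and 347 changed at least 2-fold.

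Inflammatory mediators were lower in transformed KRT8-traced cells in 11 of 19 and higher in 2, also adjusted over the list alone. Tnfaip3 fell from 243 to 45.7 CPM (-2.41), Nfkbia from 673 to 177 (-1.93) and the interferon-induced chemokine Cxcl10 had a log2 fold change of -3.43. The camera adjusted p was 7.32e-06 (adjusted p = 0.315 with an estimated correlation). Immune cell markers were higher in 10 of 12 and lower in 0, also adjusted over the list alone (camera adjusted p = 1.28e-09; adjusted p = 0.0284 with an estimated correlation), with the leukocyte phosphatase Ptprc at 6.01 (5.75 ± 0.821 CPM in transformed cells) and Laptm5 at 4.69. Class II antigen presentation genes were higher in 4 of 6, with Cd74 at 4.23 and H2-Ab1 at 3.62 (camera adjusted p = 0.00291; adjusted p = 0.315 with an estimated correlation). Endothelial markers were higher in 11 of 12 (12 adjusted over the list alone), with the endoglin gene Eng at 1.38 and Egfl7 at 1.78 (camera adjusted p = 6.72e-07; adjusted p = 0.315 with an estimated correlation). Mesenchymal transition genes were higher in 5 of 14, with the protease inhibitor gene Serpine1 at 2.25 and Snai2 at 1.46 (camera adjusted p = 0.000703; adjusted p = 0.391 with an estimated correlation). Smooth muscle markers moved the same way in 2 of 11 (camera adjusted p = 0.00948; adjusted p = 0.437 with an estimated correlation), and fibroblast markers in 0 of 12 (camera adjusted p = 0.116).

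Sterol and fatty acid synthesis genes were lower in 12 of 26 and higher in 2 (13 and 3 adjusted over the list alone), with Hmgcr, the rate-limiting enzyme of cholesterol synthesis, at -1.32, Cyp51 at -1.51 and Sqle at -1.11, while Dhcr24, which acts at the end of that pathway, rose by 1.55 from 23.3 to 68.3 CPM. The camera adjusted p was 0.00948 (adjusted p = 0.544 with an estimated correlation). Ribosomal protein genes were lower in 15 of 30 (20 adjusted over the list alone), with Rplp0 at -0.95 and Rpl3 at -0.75, and in 6 with library totals alone. The camera adjusted p was 1.28e-09 (adjusted p = 0.437 with an estimated correlation). Pseudogenes of this family went both ways between the states, with mean CPM in normal and transformed libraries of 0.2145 and 92.82 for Rps3a3 and 2.082 and 0 for Rps12-ps9. Whether reads given to copies affect this list was not tested. Luminal and umbrella cell genes were lower in 7 of 25 and higher in 0 (9 and 0 adjusted over the list alone), among them the tight junction gene Cldn4 at -1.57, Grhl3 at -1.35 and Foxa1, a luminal transcription factor, at -0.62. The camera adjusted p was 0.019 (adjusted p = 0.315 with an estimated correlation), and the median of the list turned from -0.06 to 0.098 with library totals alone. Glycolysis and hypoxia genes were higher in 7 of 21 (10 adjusted over the list alone), with Gapdh at 0.64 (camera adjusted p = 0.00291; adjusted p = 0.539 with an estimated correlation). Cell cycle genes were higher in 5 of 36 and lower in 1 (2 and 1 adjusted over the list alone), with the ribonucleotide reductase Rrm2 at 1.48 (camera adjusted p = 0.00815; adjusted p = 0.586 with an estimated correlation). Mitochondrially encoded genes were lower in 3 of 8 (4 adjusted over the list alone, camera adjusted p = 0.000434; adjusted p = 0.419 with an estimated correlation), among them mt-Nd3, which shares reads with a nuclear copy and enters that test. Red blood cell genes were lower in 2 of 4 (camera adjusted p = 0.0183; adjusted p = 0.419 with an estimated correlation).

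Few p53 targets changed in KRT8-traced cells, where 1 of 27 was higher, Btg2, an antiproliferative gene, at 1.32, and 2 were lower (camera adjusted p = 0.799). Among all genes tested in this comparison, 21.14% were called. FOXO-responsive genes were higher in 1 of 14, the cell cycle inhibitor Cdkn1b at 1.92, and lower in 2, with the stress gene Gadd45a at -0.72 (camera adjusted p = 0.799). The basal, squamous, interferon, xenobiotic, immediate early and nerve lists had camera adjusted p from 0.151 to 0.67. The squamous list had a median of 0.15 and a camera direction below 0. Beyond Trac, the largest rises were in Greb1, an estrogen-regulated gene at least 561-fold higher, Ang5 (at least 355-fold), Rps3a3 (8.12), Ifi203 (5.70), BC002163 (5.58) and the hormone carrier gene Ttr (5.34). Greb1 ranged from 0.0383 to 87.6 CPM among transformed KRT8-traced libraries, Ifi203 had 48.2 CPM in replicate 1 and 0.483 to 1.45 in the others, Ang5 had 49.9 CPM in replicate 1 and 1.34 to 13.5 in the others, and Ang5, Rps3a3 and BC002163 share reads with near-identical copies. The largest falls besides Cxcl2 and Cxcl1 were in mt-Nd3, for which 1 count in transformed cells gave a ratio of 939 (95% interval 168 to 37100) and which shares reads with a nuclear copy, Cxcl3 (-5.85), Naip6 (-5.45), Arl2bp (-3.90, SE 0.14, adjusted p = 1.04e-11) and Il1a (-3.81).

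**Figure D3:**
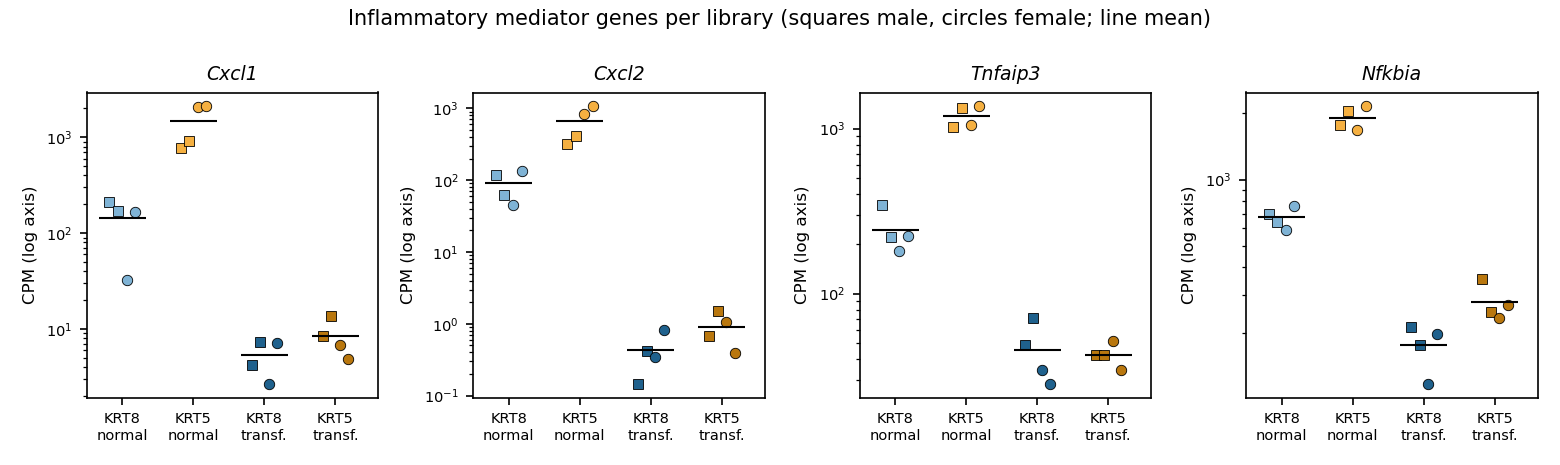
CPM of Cxcl1, Cxcl2, Tnfaip3 and Nfkbia on log axes, with each library as a square (male) or circle (female) and a line at the group mean (n = 4). All 8 transformed libraries lie below all 8 normal libraries in each gene.

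Transformed and normal KRT5-traced cells were compared with the same question. Chemokines again fell, Cxcl2 from 658 ± 353 to 0.907 ± 0.478 CPM (SD, n = 4) and Cxcl1 from 1469 ± 722 to 8.42 ± 3.72, and so did the cytokine genes Csf2, from 29.1 to 0.130, and Tnf, from 25.8 to 0.533. Fas fell from 46.1 to 5.38 CPM. Some genes of umbrella cells rose, Upk3a from 1214 ± 288 to 2828 ± 843 CPM, Krt20 from 48.4 ± 17.6 to 127 ± 5.31 and Psca from 63.9 to 399. Krt5 also rose, from 1273 ± 226 to 2369 ± 522 CPM. The log2 fold changes were -9.57 (SE 0.58, adjusted p = 1.2e-08) for Cxcl2, -7.46 for Cxcl1, -3.11 (SE 0.32, adjusted p = 2.74e-06) for Fas, 1.22 (adjusted p = 0.000973) for Upk3a, 1.40 (adjusted p = 0.000521) for Krt20, 0.73 (adjusted p = 0.0103) for Upk2 and 0.90 (SE 0.17, adjusted p = 0.000432) for Krt5. Trp63 had a log2 fold change of -0.41 (adjusted p = 0.103) and Krt8 of -0.02 (adjusted p = 0.927). In total 3430 genes were higher and 3143 lower, of which 1703 and 1071 changed at least 2-fold.

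Inflammatory mediators were lower in transformed KRT5-traced cells in 14 of 19 and higher in 2, also adjusted over the list alone (camera adjusted p = 1.13e-06; adjusted p = 0.243 with an estimated correlation), with Tnfaip3 falling from 1191 ± 181 to 42.7 ± 6.98 CPM and Nfkbia from 1914 ± 222 to 277 ± 52.6. Immediate early and heat shock genes were higher in 13 of 18 and lower in 3 (14 and 3 adjusted over the list alone), with the transcription factor Fos at 1.65 and the chaperone Dnajb1 at 1.91 up and Ier3 at -2.01 down. That list had a camera adjusted p of 0.0345 (adjusted p = 0.821 with an estimated correlation), and 9 were higher and 3 lower without the 3 libraries that stand apart. Of 27 p53 targets, 8 were lower and 6 higher, with Fas and Trp53inp1 (-2.10), a pro-apoptotic gene, lower and Btg2 higher at 1.42. Among all genes tested in this comparison, 46.35% were called. FOXO-responsive genes were higher in 4 of 14 and lower in 4 (4 and 5 adjusted over the list alone), with Gadd45a at -1.68 and the transcriptional regulator Cited2 at -2.16 down and the ubiquitin ligase gene Fbxo32 at 1.05 up. Sterol and fatty acid synthesis genes were lower in 12 of 26 and higher in 6, with Hmgcr at -2.07, Mvd at -1.61 and Dhcr24 at 1.57 (camera adjusted p = 0.0774).

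Luminal genes were higher in 5 and lower in 5 of 25, with Psca at 2.64 and the epithelial transcription factor Elf3 at -0.81, and basal genes were higher in 3 and lower in 7 of 22, with the growth factor receptor Egfr at -1.32 and the water channel Aqp3 at -0.78. Squamous differentiation genes were higher in 7 of 15, with Fam25c at 3.41, Krt6a at 2.87 (1.51 without KRT5 transformed replicate 3) and Krt10, a keratin of suprabasal epidermis, at 1.89, and in 3 of 15 without the 3 libraries that stand apart. Interferon response genes were higher in 11 of 24 and lower in 1, with the antiviral gene Rsad2 at 2.14, while Cxcl10 was lower at -3.81. Xenobiotic genes were higher in 4 and lower in 4 of 19, with heme oxygenase Hmox1 at 2.35 and Cyp1b1 at -2.92. Glycolysis genes were higher in 5 of 21, with Gapdh at 0.87, and mesenchymal genes in 4 of 14, with Serpine1 at 1.96. These lists and the ribosomal, mitochondrial, cell cycle and fibroblast lists had camera adjusted p from 0.0943 to 0.984, except the ribosomal list at 0.0774. The median and the mean differed in sign for the luminal (-0.02 and 0.13), p53 target (0.08 and -0.18), FOXO (0.04 and -0.20) and xenobiotic (0.12 and -0.17) lists, and the ribosomal median turned from -0.17 to 0.027 with library totals alone.

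Markers of other cell types moved with the state in KRT5-traced cells too. Endothelial markers were higher in 12 of 12, with Eng at 2.47 and Pecam1, an endothelial adhesion gene, at 2.42 (camera adjusted p = 4.88e-05; adjusted p = 0.555 with an estimated correlation). Immune cell markers were higher in 9 of 12 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.49e-05; adjusted p = 0.243 with an estimated correlation), with Ptprc at least 102-fold and Cd3g at least 48.6-fold higher and Trac at 6.98. Class II genes were higher in 4 of 6 (5 adjusted over the list alone), with Cd74 at 3.64 (camera adjusted p = 0.0345; adjusted p = 0.555 with an estimated correlation). Smooth muscle markers were higher in 5 of 11 (6 adjusted over the list alone, camera adjusted p = 0.0163; adjusted p = 0.708 with an estimated correlation) and red blood cell markers in 4 of 4 (camera adjusted p = 0.0245; adjusted p = 0.555 with an estimated correlation). Of 4 nerve and Schwann cell markers 2 were higher, and the myelin gene Mbp was lower at -1.74. Fibroblast markers were called in 0 of 12, and in 9 of 12, all higher, without the 3 libraries that stand apart, where 7 of 14 mesenchymal genes were higher. The largest rises by the naming rule were in Rps3a3 (9.80), which shares reads with copies, Trac, Ttr (5.69), the Rac activator Prex1 (4.44, SE 0.36, adjusted p = 2.64e-07), Arc (4.22), Edn2 (3.94) and Ak1 (3.90). After Cxcl2, the largest falls were in Csf2 (-7.75), Cxcl1, the sugar transporter Slc2a6 (-6.66), Cxcl3 (-5.88), the epithelial cytokine Il17c (-5.78) and Tnf (-5.53). The Krt14 change of 3.88 (adjusted p = 0.019) rested on transformed libraries from 18.9 to 758 CPM, and without KRT5 transformed replicate 3 it was 2.16 (adjusted p = 0.129). Without KRT5 transformed replicate 1 the Upk2 change was 0.40 (adjusted p = 0.0735).

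The responses of the lines shared many genes and differed in others. Of the genes called, 956 were higher in transformed cells of both lines and 1199 lower, where independence would give 350 and 344, and 32 were called in opposite directions. Both contrasts share the dispersions and the filter of the same fit, so independence is not a strict reference. A difference in processing between the states would also enter both lines. Across 14180 genes, which are not independent replicates, the log2 fold changes of the lines had r = 0.671 and rho = 0.637. A direct test of the difference between the responses called 537 genes, 244 with a higher and 293 with a lower change in KRT5-traced cells. The change of Krt20 was higher in KRT5-traced cells by 1.84 (SE 0.37, adjusted p = 0.013), and that of Psca by 2.02 (SE 0.45, adjusted p = 0.021). The change was lower in KRT5-traced cells for Irf1, an interferon-induced transcription factor (-3.69, SE 0.39, adjusted p = 0.000176), Icam1 (-3.35), Tnfaip3 (-2.39), Fas (-2.34), Cited2 (-2.33) and Bcl2l11 (-1.61), each from a higher level in normal KRT5-traced cells. The differences for Upk2 (0.52, adjusted p = 0.301) and Trp63 (-0.90, adjusted p = 0.0825) did not pass the test.

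Inflammatory mediators differed between the responses in 3 of 19 genes, all with the lower change in KRT5-traced cells (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00117). Luminal genes differed in 3 of 25, all with the higher change in KRT5-traced cells (6 and 1 adjusted over the list alone, camera adjusted p = 0.0339), basal genes in 1 in each direction (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0129) and squamous genes in 1 (2 adjusted over the list alone, camera adjusted p = 0.0328). Cell cycle and ribosomal protein genes had 0 members called by edgeR over all genes and 0 adjusted over the list alone, with camera adjusted p of 0.00117 for each, toward KRT8-traced and KRT5-traced cells. Each of these lists had adjusted p = 0.754 with an estimated correlation. Red blood cell genes differed in 4 of 4 (camera adjusted p = 7.07e-06; adjusted p = 0.22 with an estimated correlation). The other lists had camera adjusted p from 0.16 to 0.802, and the camera direction was opposite to the median of the fibroblast (-0.56) and immune (above 0) lists. The largest differences by the naming rule were in Ndufs5 (3.47), Sprr2g (3.44), Ern2 (3.33), Gcnt3 (2.81) and Klhl14 (2.68), and in Cd200r4, Cd200r1, Ugt1a8, Slc2a6 (-3.78) and Irf1. Ndufs5, Sprr2g and the Cd200r genes share reads with related copies, and the Cd200r and Ugt1a8 values depend on the prior count, with 0 or 1 counts in normal KRT8-traced cells. Leaving out 1 library ended the Ern2 call in 7 fits (adjusted p up to 0.0753) and the Ugt1a8 call in 12 (up to 0.11), and Cd200r4 lost its call without KRT8 transformed replicate 1 (adjusted p = 0.0773). The number of genes called was 251 without KRT8 normal replicate 2 and 1008 without KRT5 transformed replicate 2.

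**Figure D4:**
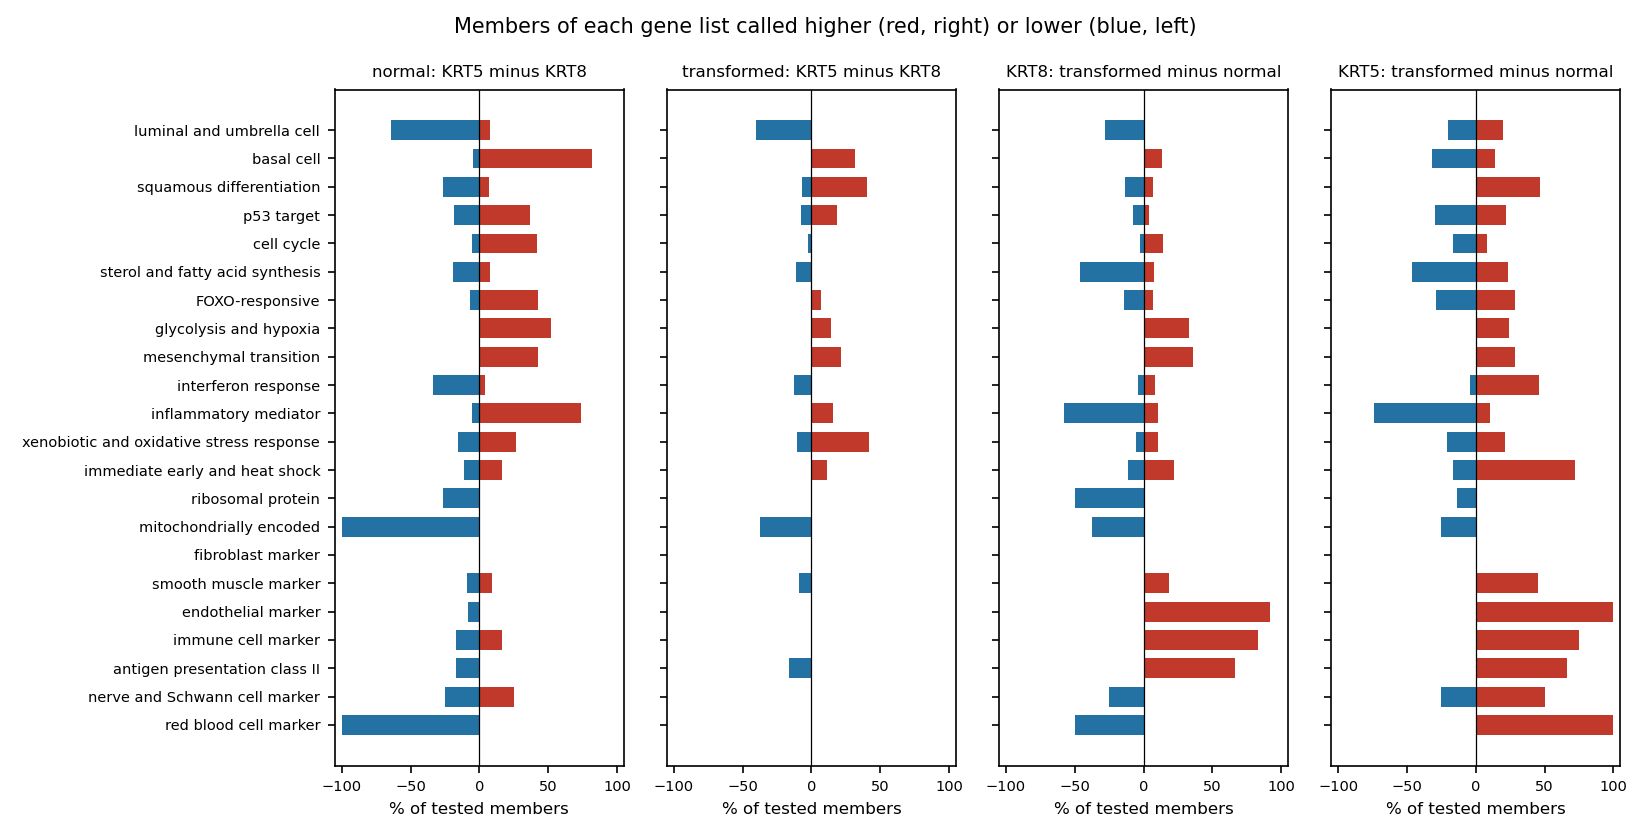
Percent of the tested members of 22 gene lists called higher (red, right of 0) or lower (blue, left of 0) at an adjusted p under 0.05, for the 4 comparisons of 2 groups. Inflammatory mediators are higher in normal KRT5-traced cells in 14 of 19 genes and lower after transformation in 11 of 19 in KRT8-traced and 14 of 19 in KRT5-traced cells.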

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

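The tests of the immune marker pattern, of the inflammatory mediator pattern and of the summed copies of mt-Nd3 were chosen after the results they concern were seen, whereas the pseudogene share and the splits of the libraries were fixed earlier. The criteria for the stress of dissociation and for fewer immune cells were also revised after their values were seen.

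Immune cell markers were near 0 in the 8 normal libraries and at similar levels in the 8 transformed ones, and the 9 members higher in both lines summed to 0.221 to 3.42 CPM and 28 to 40.7 CPM. Reads from a library pool sequenced alongside, tested as an equal mix of the markers in every transformed library, gave a chi-square of 2.7 per degree of freedom, between the bounds of 1.5 and 3 set for an equal and an unequal mix, with Lyz2 at 11.1 and the other 8 genes at 0.391 to 2.48. The bound of 3 was passed by an earlier test on all 12 members (4.85), which included Cd68, a macrophage gene that normal libraries also had, so it was redone on the 9. Lower purity of the sort would raise immune and endothelial markers alike. The log2 ratio of the 9 members to endothelial markers rose by 2.28 without overlap of the states. These 9 had been picked as higher in transformed cells of both lines, so a rise was largely fixed in advance. The whole immune list went from a mean sum of 22.6 CPM in normal to 49.9 in transformed libraries. Endothelial markers already summed to 31.6 CPM in normal libraries and reached 106, so the whole immune list rose less. Against fibroblast markers the same 9 members rose by 2.46 with overlap of the states and the whole list by 0.26. Neither explanation could be excluded, and more T cells in transformed urothelium, which a sort for YFP should remove, may be a biological explanation that was not tested.

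Inflammatory mediator genes were lower in transformed libraries of both lines. Stronger stress of dissociation in normal libraries would raise immediate early and heat shock genes there, and in KRT5-traced cells 13 of these were higher and 3 lower in transformed libraries (exact binomial two-sided p = 0.0213), but 9 and 3 without the libraries that stand apart (exact p = 0.146), and the test treats genes that move together as independent, so this stays open. In KRT8-traced cells the same test (4 higher, 2 lower, exact p = 0.687) decided nothing. Fewer immune cells in transformed libraries would lower immune markers, but the smaller of the line medians was 3.88, with 0 members called lower over all genes. That rise cannot count against this explanation, since reads from another pool or a less pure sort could have made it. The general leukocyte gene Ptprc had 0 counts in normal KRT5-traced cells, where Cxcl1 had 780 to 2102 CPM. Lyz2 and C1qb had at most 0.612 and 0.171 CPM in any normal library. These levels argue against immune cells as the source of the mediators in normal KRT5-traced cells. Cd68 (4.52 to 39.6 CPM) and Itgam (0.67 to 2.87 CPM) were present in normal libraries. The macrophage gene Cd68 had -0.33 in KRT8-traced and -0.78 in KRT5-traced cells. For KRT8-traced cells the question stays open. Time since tamoxifen, age and batch could account for the fall as well as the targeting of Trp53 and Pten, since 0 normal libraries were taken 3 months after tamoxifen.

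Some genes were listed near 0 in all libraries of 1 state while a near-identical copy was near 0 in the other. The mitochondrial gene mt-Nd3 had 6.1 to 15.4 CPM in normal and at most 0.0496 in transformed libraries, and its nuclear copy Gm28438 had at most 0.0552 and 5.9 to 15.3. Their sum was 11.1 ± 3.56 CPM (SD, n = 8) in normal and 10.8 ± 2.96 in transformed libraries, and its log2 change lay 0.29 from the median of the other mitochondrial genes, which is consistent with reads given to a different copy in each state. Pseudogenes made up 19.9% of the 161 genes that separated all normal from all transformed libraries over 8-fold, against 2.2% of the others, a ratio of 9.02 (Fisher's exact p = 1.31e-20), where chance would separate 0.0155% of genes at any fold. The genes compared were not matched for expression level, so low counts may account for part of that ratio. A different alignment or annotation between the states may still have shaped calls of copies such as Rps3a3, and no biological explanation was tested.

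The counts of genes called between 2 groups were compared with those of other splits of the same libraries. The real split called the most genes in each comparison, a share of 0.0286, the lowest that 35 splits can give. Other splits mix the groups, which raises the fitted spread, so the gap in counts does not measure the strength of this evidence. In KRT8-traced cells the real split called 2997 genes and the highest other split of 35 called 0, and in KRT5-traced cells 6573 and 200 (1 split as large in each, the real one). For normal lines the values were 5578 and 1, and for transformed lines 1268 and 328. For the difference of responses 4 of 100 splits called as many as the real 537, the real one among them, and the highest other called 3421. The 3 splits that called more genes than the real one kept the normal lines apart and exchanged 1, 2 or 3 of 4 transformed libraries between the lines. In such splits the contrast still holds the difference between the normal lines, where 5578 genes were called. These splits are thus no measure of chance for the difference of responses, and their share decides nothing.

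A library far from the other 3 of its group was found in 30 of 372 groups of values, where chance gives about 1 in 20. That rate assumes independent values, whereas these come from related genes and lists in the same libraries. A single count against 0 in the others also passes the rule, as for Nrcam, Ugt1a8 and mt-Nd3. The excess over that rate is thus not a test. Total counts were 24.3 M in KRT8 transformed replicate 3 against 13 to 14.4 M in the others, and mitochondrial counts 3.45% in KRT8 transformed replicate 2 against 2.17 to 2.39%. In KRT5 normal replicate 1 the mean log2 CPM was 7.67 for glycolysis genes (others 7.32 to 7.36), 3.57 for mesenchymal genes (2.08 to 2.17) and 1.71 for endothelial markers (0.362 to 0.407). Endothelial markers were at 1.48 in KRT8 normal replicate 4 (0.823 to 0.868), and nerve markers at 1.99 in KRT5 transformed replicate 1 (1.62 to 1.67). In KRT5 normal replicate 2, Pten had 90.7 CPM (74 to 75.9) and Itga3 398 (588 to 608). In KRT5 normal replicate 3, Upk3a had 1640 CPM (1040 to 1110), Cd200r4 0.067 (22.3 to 30.8) and Cd200r1 0 (21.1 to 29.2). In KRT5 transformed replicate 1, BC002163 had 0.927 CPM (9.55 to 12.4), Dll1 19.4 (45.3 to 51), Sprr2g 54.4 (79.9 to 81.4) and Grhl3 295 (334 to 341). In KRT8 normal replicate 3, Cxcl1 had 32.3 CPM (167 to 210), Dmgdh 17.6 (11.4 to 12.2), Shisa9 20.5 (13.1 to 13.6) and Aldh3b3 2.37 (0.884 to 1.03). KRT8 normal replicate 4 had 0.0522 CPM of Nrcam and of Ugt1a8, each 0 in the others, and KRT8 normal replicate 1 had 25.5 CPM of Ndufs5 (33.3 to 34). KRT8 transformed replicate 1 had 26.7 CPM of Cd200r4 (0.0689 to 0.276) and 27.7 of Cd200r1 (0.192 to 0.483), and replicate 2 had 0 CPM of Fgfbp1 (0.276 to 0.307). KRT8 transformed replicate 3 had 198 CPM of Cyp1a1 (15.6 to 20.9) and 13.5 of Ugt1a8 (5.79 to 6.49). For mt-Nd3, that library had 0.0383 CPM and KRT5 transformed replicate 4 had 0.0496, each with 0 in the others of its group.

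A direct test found that responses to transformation differed between the lines in 537 genes, and the values here are KRT5-traced minus KRT8-traced log2 changes. They were -1.78 for Trp53, -0.80 for Pten, 1.84 for Krt20, 2.02 for Psca, -2.67 for Cxcl1, -2.39 for Tnfaip3, -3.35 for Icam1, -3.69 for Irf1 and 2.66 for Prex1. They were -3.78 for Slc2a6, -2.68 for Dll1, -3.47 for Guca2a, 2.81 for Gcnt3, 3.44 for Sprr2g, 1.74 for Shisa9, 3.33 for Ern2, 3.47 for Ndufs5 and 2.68 for Klhl14. Fitted values of -16.4 for Cd200r4, -16.12 for Cd200r1 and -6.96 for Ugt1a8 rest on 0 or 1 counts in a group and depend on the prior count. The Cxcl1 difference ended in 10 of the fits that left out a library (-2.99 to -2.34). Lists that differed in camera had adjusted p of 0.0339 for luminal, 0.0129 for basal, 0.0328 for squamous, 0.00117 each for cell cycle, inflammatory and ribosomal, and 7.07e-06 for red blood cell genes, and none of these calls held with an estimated correlation.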

How the results depend on the processing

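The fits without the 3 libraries that stand apart (KRT5 normal replicate 1, KRT5 transformed replicates 2 and 3) and with protein-coding genes only were chosen after the data were seen, and the other alternatives before.

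Counts of genes called stayed within 1.5 times in 155 comparisons with an alternative and moved further in 36. Of the values for named genes, 15504 either kept their call and direction or were uncalled in both fits, whatever their sign. A further 1061 lost their call, 231 gained a call, and 4 that were called in at least 1 of the fits reversed. Of 45 list calls, 2 held with an estimated correlation, the highest p of the alternatives for all 45, and fry lost 18 and gained 9. DESeq2 gave 1196 genes for the difference of responses, and a filter at 10 CPM gave 1915 in KRT8-traced cells, with fewer genes tested. With RIN as a term, which goes with the line, 642 genes were called between normal and 75 between transformed lines, and Cxcl5 between transformed lines reversed to -0.0874. Against a fold of 1.5 the counts were 656 (KRT8-traced), 2267 (KRT5-traced), 1556 (normal lines), 172 (transformed lines), 71 (difference of responses) and 431 (overlap), with Trp53 in KRT8-traced cells at -0.72 no longer called. Male mice alone, with fewer libraries, gave 893, 2772, 1258, 138, 2 and 476 in the same order, with Tgm1 between transformed lines reversed to -0.0277. Female mice alone gave 1051 (KRT8-traced), 287 (difference) and 811 (overlap), with Slc16a3 in KRT8-traced cells reversed to -0.18 and Lum between normal lines to -2.33. The cause of the 4 reversals was not tested. Without the libraries that stand apart 475 genes were called between transformed lines and 1794 for the difference. Leaving out each library gave 2110 to 3207 genes in KRT8-traced cells, 5507 to 6745 in KRT5-traced cells, 4424 to 5739 between normal lines, 712 to 1431 between transformed lines, 251 to 1008 for the difference and 1569 to 2270 for the overlap, and -0.82 to -0.61 for Trp53 in KRT8-traced cells. Library totals alone moved the median log2 change of all genes from 0.0262 to 0.183 in KRT8-traced and from 0.0849 to 0.283 in KRT5-traced cells, and 4 list calls in KRT5-traced cells were lost. No paired analysis was possible because replicate numbers follow the order of the samples and each mouse gave 1 library. At this depth changes of 1.5-fold were recovered for 14% of genes in the simulation, which changed far fewer genes than were called here. Genes under the count filter were not tested.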

Other observations

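The sex comparison was added after the results were seen, as was the choice of the genes described here, while the tests of chromosome blocks and of the floxed genes were fixed before.

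Some T cell genes outside the lists, picked from the genes that separate the states, were near 0 in normal libraries. Mean CPM in normal and transformed libraries was 0.0192 and 2.4 for Cd4, the co-receptor of helper T cells, 0.0368 and 2.90 for Itk, a kinase of T cell receptor signaling, and 0.106 and 2.47 for Icos, a costimulatory receptor. The inhibitory receptor gene Ctla4 had 0.0427 and 1.43. Skint genes, a family expressed in skin and thymus epithelium, went both ways, with Skint4 at 1.83 and 0 and Skint7 at 1.99 and 0.00862 CPM, and Skint5 at 0.227 and 7.55 and Skint6 at 0.110 and 3.6. Members of that family share sequence, so reads may be exchanged between them. Pseudogenes were over-represented by a ratio of 9.02 among genes that separate the states, without matching for expression level.

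Some genes set the lines apart in both states. Msln, a cell surface glycoprotein gene, was higher in KRT5-traced cells by 4.38 in normal and 6.70 in transformed cells (log2), the serotonin transporter gene Slc6a4 by 5.18 and 3.6, and Esr1 by 2.55 and 3.38. Bhmt2 had -4.90 and -3.56 and its neighbour on chromosome 13, Dmgdh, -4.85 and -3.65. Between male and female mice, with sex as an additive term, 11 genes were called and 4 of them lie on autosomes. Adamts1, a secreted protease gene, had 114 CPM in males and 53.5 in females (1.13, SE 0.17, adjusted p = 0.00714) and the alcohol dehydrogenase Adh7 59.2 and 33.9 (0.83, SE 0.14, adjusted p = 0.0365). Agr2, a mucin chaperone gene, had 6.65 and 12.8 (-1.22, SE 0.21, adjusted p = 0.0312) and Aldh1l1, an enzyme of folate metabolism, 15.4 and 24.5 (-0.66, SE 0.12, adjusted p = 0.0441).

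Blocks of linked chromosome that differ between the mouse lines are a candidate explanation for line differences present in both states. The set tested held the 363 genes of known position called in both states in the same direction, each over 2-fold in both. Of these, 158 had another within 1 Mb, against a median of 148 and a 95% point of 166 in 10000 random draws, so clustering was neither shown nor excluded. Chromosome segments carried along with the floxed alleles might change genes near Trp53 and Pten in both lines. Within 10 Mb of them 4.57% of 394 genes were called in both lines with a 2-fold change, against 5.71% of the others, an odds ratio of 0.791 (95% interval 0.461 to 1.28, Fisher's exact two-sided p = 0.378), and the interval spans equality.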
